A study of Mus musculus with 2 samples.

How the data were processed

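ATAC-seq, which maps open chromatin by the insertion of the Tn5 transposase, was measured in regulatory T cells of the mouse. Per the labels, the 2 libraries are technical replicates of 1 biological replicate, taken from a 4-month-old male, so all values describe 1 sample and no spread between animals could be given. The labels name 1 group, and no comparison between groups exists.

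The authors deposited 3 peak lists on the mouse assembly mm10, and per the file listings of both libraries the lists came from an alignment that the libraries share. Peaks were therefore called on pooled reads, and no value per library was used here. The aligner, the peak caller, their versions and any shift of the read ends for the transposase are not given in the sources used here. Nor is the local or genome-wide background against which enrichment was computed, which matters because a background taken near a peak lowers the enrichment of peaks beside other peaks. Each deposited list gives, per line, an interval, a summit, a signal value of enrichment and a −log10 p, with column order taken from the narrowPeak format. The signal is the authors' own enrichment value per peak, its reference is not stated, and it was used only to describe, rank or filter peaks within a list. The deposited −log10 p was used in the same way. The ranked list also holds the −log10 of the irreproducible discovery rate (IDR), a measure of how well peak ranks agree between replicate calls, and the −log10 p of 2 inputs. The sources used here do not state whether those inputs were the technical replicates or random splits of the reads. The depth of the libraries is unknown because the lists hold no read counts.

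The IDR-thresholded list was the main peak set. Lines that shared an interval were reduced to 1 peak, represented by its summit of highest signal, and coordinates are 1-based. The reference was GRCm38.p6 with the GENCODE M21 annotation, which is the same assembly as mm10. Chromosome names and lengths were checked, and all peaks of the main list lay within the 21 chromosomes used (1 to 19, X and Y). A summit within 1 kb of any annotated transcription start site (TSS) was called promoter, and the other summits were called exonic, intronic or intergenic in that order. The shares were set against 100 draws of random positions on the same chromosomes, outside assembly gaps. A gene had a promoter peak when a peak overlapped the window of 1 kb on either side of a TSS of any of its transcripts. Such a TSS can lie inside the gene, away from its 5′ end. The locus of a gene was the gene and 20 kb on either side.

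The 19 gene lists and 28 consensus motifs were fixed before the data were examined. Of 292 list entries, 291 matched a protein-coding gene, and the exception, Clec7a, has another biotype in the annotation. For each list the share of genes with a promoter peak was given with an exact Clopper-Pearson 95% interval and with its percentile among 10000 random lists of protein-coding genes of the same size. The median number of peaks per locus was ranked in the same way among random lists matched on locus length in 20 bins. A list was called above or below random lists when its percentile lay outside the central 95%. Motifs were searched on both strands in 200 bp windows centred on summits and in windows 1 kb away on both sides. Standard errors are jackknife SE over chromosomes, leaving out each chromosome in turn. A motif was called enriched or depleted when its ratio differed from 1 by more than 1.96 SE. Peaks and genes are not replicates, so no p-value was computed, and intervals and jackknife SE cover counting error and variation along the genome only.

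Genes named in the text followed a rule set before the data were examined: Foxp3, Il2ra, Ctla4, Ikzf2, Tnfrsf18, Cd4 and Cd8a always, and from each list the 3 genes with the highest promoter signal and up to 3 without a promoter peak in list order. The 10 genes with most peaks per locus and the 10 peaks of highest signal were also named. Other names were chosen after their values were seen and are marked so. A few genes that this rule selects, and 1 test on B cell genes, are not reported here.

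The functions were tested on simulated data. With 20000 simulated summits made with 43.8% in promoters, 43.8% were recovered. Of 500 neutral lists of genes, 5.20% lay outside the central 95%, and all 200 lists with a planted share of 90.0% lay above it. A RUNX motif planted in 20000 windows at a ratio of 2.10 gave 2.09, and AP-1, which was not planted, gave 1.02. A simulated strength ratio of 2.00 gave 1.97, and 200 of 200 simulated locus counts equalled a direct search.

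Alternatives fixed before the data were examined numbered 28. They used the pseudoreplicated list, peaks with at least the median signal, every line, an overlap of 50% of both intervals, promoter windows of 500 and 2500 bp, TSSs of protein-coding genes or 5′ gene ends only, and random lists matched in 10 bins on promoter CpG ratio, taken within 1 kb of the 5′ gene end. They also used loci with 5 or 50 kb on either side, motif windows of 100 bp, comparison windows 5 kb away and windows that were not mostly repeat-masked. Another 5 were chosen after seeing the data: lists without genes that have a coding neighbour's TSS within 2 kb, peaks with at least the median −log10 p for promoters and for loci, dinucleotide-shuffled windows for motifs, and −log10 p in place of signal for peak strength. Matches to the mitochondrial genome were found with blastn over at least 100 bp at an identity of at least 90%. The tools were Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, bedtools 2.31.1 and blastn 2.17.0. The file listings hold no measurement and gave only the description of the lists.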

Results

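Open chromatin of mouse regulatory T cells, the Foxp3-dependent CD4 lineage that restrains immune responses, was profiled by ATAC-seq. The cells were primary cells of an adult male aged 4 months, from a cross that carries a tamoxifen-inducible Cre at Foxp3 and a YFP reporter at Rosa26, and the labels trace them to haematopoietic cells of the bone marrow. Both libraries, technical replicates of 1 biological replicate, entered the same pooled peak lists. No other cell type or condition was sampled, so each value is a description of this pool, and the depth of the libraries is unknown.

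The IDR-thresholded list held 34610 peaks with a median width of 668 bp (interquartile range 453 to 937 bp). They covered 25.03 Mb, or 0.918% of the chromosomes. Their median signal, the authors' enrichment value per peak, was 13.2 (interquartile range 8.98 to 18.2, full range 1.495 to 64.7). More than 1 summit was listed in 19470 of the peaks. The longer pseudoreplicated list held 58871 peaks with a median signal of 8.55. Of the thresholded peaks, 34564 (99.9%) overlapped a peak of the pseudoreplicated list by at least 1 bp, and 58.7% of the pseudoreplicated peaks overlapped a thresholded one. In the ranked list, 68653 of 99272 lines were those of the thresholded list, whose lowest −log10 IDR was 1.301. Across the lines of the ranked list, the −log10 p of the 2 IDR inputs had a Spearman correlation of 0.779. This is a correlation across peaks, which are not independent replicates.

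Promoters took the greatest share of open sites in the thresholded list of these cells. Summits within 1 kb of a TSS numbered 13691, or 39.6% ± 1.23 (jackknife SE) of the 34610 peaks, 6.25 times the 6.33% of random positions. Introns held 11289 peaks (32.6% ± 0.679), against 40.1% of random positions, and intergenic sequence held 8479 (24.5% ± 0.810), against 50.1%. Exons outside promoters held 1151 peaks (3.33% ± 0.145), close to the 3.40% of random positions. The promoter excess and the intron and intergenic deficits lay outside the range of all 100 random draws. Introns led with the pseudoreplicated list (38.3%, against 30.9% in promoters) and with promoters within 500 bp (35.5%, against 34.6%). The exon ratio of 0.978 changed side, to 1.16, with the pseudoreplicated list.

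**Figure D1:**
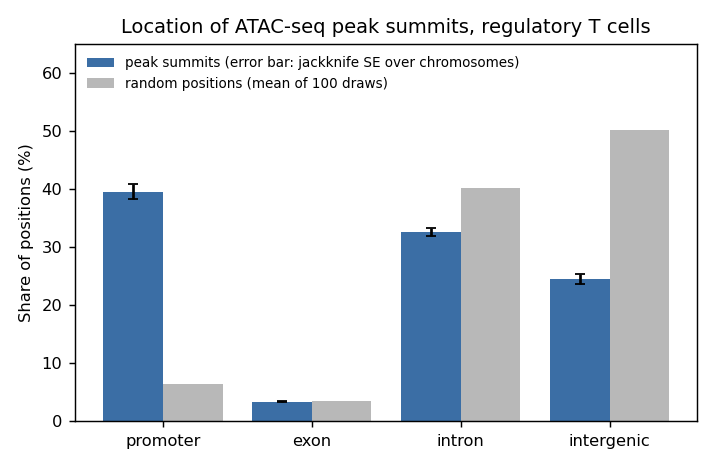
Share of peak summits (%) in each annotation class, blue bars with jackknife SE over chromosomes, beside the mean share of random positions over 100 draws, grey bars. Promoters held 39.6% of summits and 6.33% of random positions.

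Genes that define T cells and regulatory T cells mostly had open promoters. Of the 22 genes of the Treg signature list, which holds Foxp3 and the receptors and transcription factors that mark the lineage, 19 had a promoter peak (86.4%, exact 95% interval 65.1 to 97.1%). Entpd1, an ectonucleotidase that degrades ATP, had the highest promoter signal of the list (26.3), followed by the costimulatory receptor Icos (15.6) and the actin-capping protein gene Capg (14.99). A TSS of the neighbouring gene Tctn3 lies within 2 kb of a TSS of Entpd1, so that peak is not specific to Entpd1. Itgae, Ebi3 and Il10 had no promoter peak, although Itgae had 8 peaks in its locus, Ebi3 3 and Il10 4. The T cell identity list had promoter peaks at 21 of 23 genes (91.3%, 72.0 to 98.9%), led by the signalling adaptor Lat (22.3), the CD3 chain gene Cd3g (17.2) and the transcription factor Bcl11b (16.0). Tcf7 and Skap1 were without. With 5′ ends of genes only, the share of T cell identity genes was 73.9% (percentile 99.2 of random lists). Across all 21911 protein-coding genes, 11521 (52.6%) had a promoter peak. Among random lists of the same size, the Treg signature stood at percentile 99.9 and T cell identity at percentile 99.985. With only the peaks of at least the median signal, the Treg signature fell below random lists (percentile 0.455) and T cell identity stood at percentile 50.2. With only the peaks of at least the median −log10 p, chosen after seeing the data, they stood at percentiles 95.9 and 99.7.

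Other T cell programs differed in how many promoters were open. All 15 genes of the activation and NF-kB list had a promoter peak (interval 78.2 to 100%), among them Nfkb1 (16.9), the orphan nuclear receptor Nr4a1 (15.9) and Egr2 (13.2). Of 31 cytokine and chemokine receptors, 24 had a promoter peak (77.4%, 58.9 to 90.4%), with high signals at the common gamma chain gene Il2rg (18.9) and the interferon-gamma receptor gene Ifngr1 (17.0). Il12rb2, Il1rl1 and Ifngr2 were among those without. Of 8 inhibitory receptors 7 had a promoter peak, including Tigit (11.1), Cd160 (9.08) and Btla (8.64), and Lag3 had none. The peak of Nfkb1 (135594157 to 135594940) lay near a TSS inside the gene, far from its 5′ end at 135691547. Those of Nr4a1, Egr2 and Cd160 also lay more than 1 kb from the 5′ end. With 5′ ends only, 93.3% of the activation list had a promoter peak. Helper T cell cytokines had few promoter peaks in the thresholded list: 2 of 13 had a promoter peak (15.4%, 1.92 to 45.4%), Ifng (13.7) and Il2 (10.5), while Il3, Il4 and Il5 had none. The activation list stood above all random lists, the receptors at percentile 99.7 and the helper cytokines at percentile 0.375. Peaks of at least the median signal put the activation list at percentile 1.65 and the receptors at 21.7, and lists matched on promoter CpG ratio put the helper cytokines at 25.8. With the pseudoreplicated list, 38.5% of the helper cytokines had a promoter peak (percentile 8.56), and the call ended.

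The effector or tissue Treg list and the resting T cell list did not leave the central 95% of random lists. Of 17 effector genes, 11 had a promoter peak (64.7%, 38.3 to 85.8%; percentile 83.8), led by Prdm1, which encodes Blimp-1 (22.98), the growth factor gene Areg (20.9) and Batf (16.0). Il1rl1, Klrg1 and Cxcr3 were without. Of 12 genes of resting cells and lymph node homing, 9 had a promoter peak (75%, 42.8 to 94.5%; percentile 93.2), among them Ccr7 (14.8), Klf2 (13.7) and Bach2 (12.3). Tcf7, Igfbp4 and Dapl1 were without. The inhibitory receptors stood at percentile 97.4, at the edge of the central range, and at 0.910 with peaks of at least the median signal. Both the effector and the resting list passed the upper limit with the pseudoreplicated list (percentiles 99.5 and 99.2). The lists share members: 6 effector genes, 4 genes of resting cells and 4 Treg signature genes also stand in another list.

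**Figure D2:**
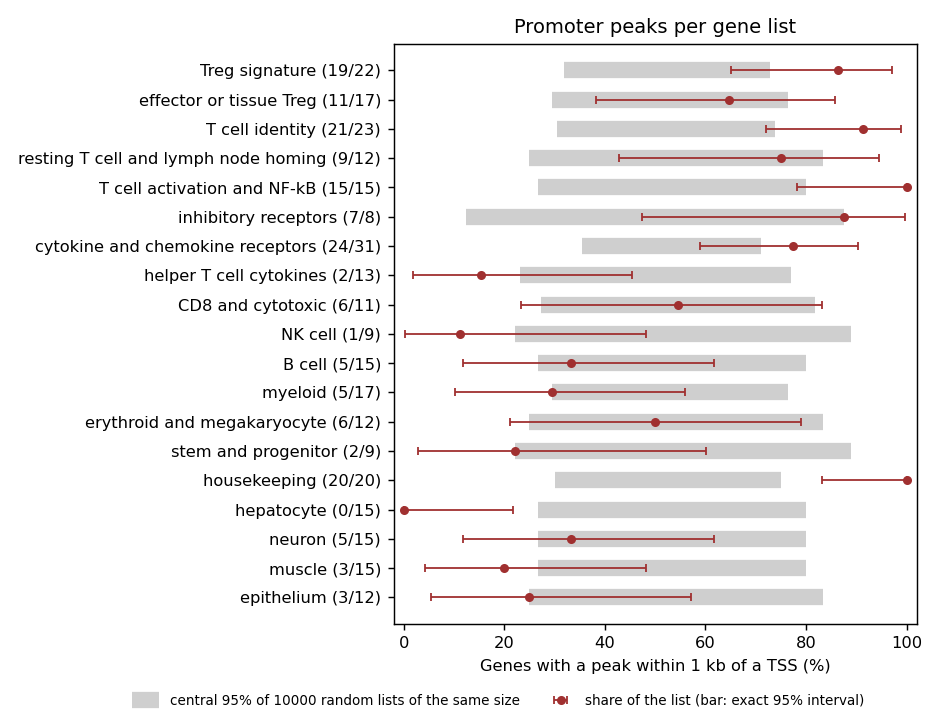
Share of genes in each list with a peak within 1 kb of a TSS (%, red points with exact 95% intervals) and the central 95% of 10000 random lists of the same size (grey bars). The Treg signature (86.4%) and T cell identity (91.3%) lie to the right of their grey bars, and hepatocyte genes (0 of 15) to the left.

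At Foxp3, which encodes the lineage's defining transcription factor, 5 peaks lay in the gene and 20 kb on either side (chromosome X, gene 7573644 to 7595245 on the plus strand, GRCm38). The peak in intron 1 of the principal transcript (7583673 to 7584422) had its summit 4.38 kb downstream of the principal TSS at 7579676 and a signal of 10.1. No thresholded peak covered that TSS, where the pseudoreplicated list had a weak peak at 7579427 to 7579796 with a signal of 1.98. The promoter peak of the gene (7574032 to 7574981, signal 9.50) was that of an alternative upstream TSS, which lies within 2 kb of a TSS of the neighbouring gene Ppp1r3f. The other 3 peaks had summits at −13.17, −7.08 and +25.75 kb from the principal TSS, and the downstream peak had the highest signal of the locus, 21.7. The peak in intron 1 and the promoter peak ranked at percentiles 31.6 and 27.9 by signal among all peaks.

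Il2ra, the gene of the interleukin-2 receptor alpha chain CD25, had 12 peaks in its locus on chromosome 2 (gene 11642807 to 11693193). Its TSS peak (11642244 to 11643060) had a signal of 9.67 and the strongest of 6 peaks in intron 1 (11663942 to 11664304) a signal of 9.84. Ctla4, an inhibitory receptor gene on chromosome 1 (60887000 to 60915832), had 14 peaks, and the peak over its principal TSS (60908773 to 60909272) had a signal of 4.98, with a −log10 p of 134.7. Ikzf2, which encodes Helios, had 18 peaks (chromosome 1, 69531214 to 69687245), with the highest signal, 15.7, in intron 6 of the principal transcript (69544000 to 69544657). No list had a peak over its principal TSS at 69685821, and its promoter peak (69682979 to 69683465, signal 5.52) lay within 1 kb of another TSS. A peak at 69686924 to 69687997 (signal 4.59) covered the 5′ end of the gene. Tnfrsf18, which encodes GITR, had 7 peaks on chromosome 4, of which the peak in exon 1 (156026175 to 156026375) had a signal of 2.69 and a peak at −3.79 kb from the TSS (156021358 to 156022693) a signal of 13.2. The lineage genes Cd4 and Cd8a, both on chromosome 6, stood apart. Cd4 had 10 peaks, including its TSS (124888112 to 124888336, signal 4.56) and intron 1 (124884938 to 124885760, signal 19.1), and Cd8a (71373427 to 71379173) had 0 peaks in its locus. These counts are of peaks called on pooled reads and carry no replicate error.

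**Figure D3:**
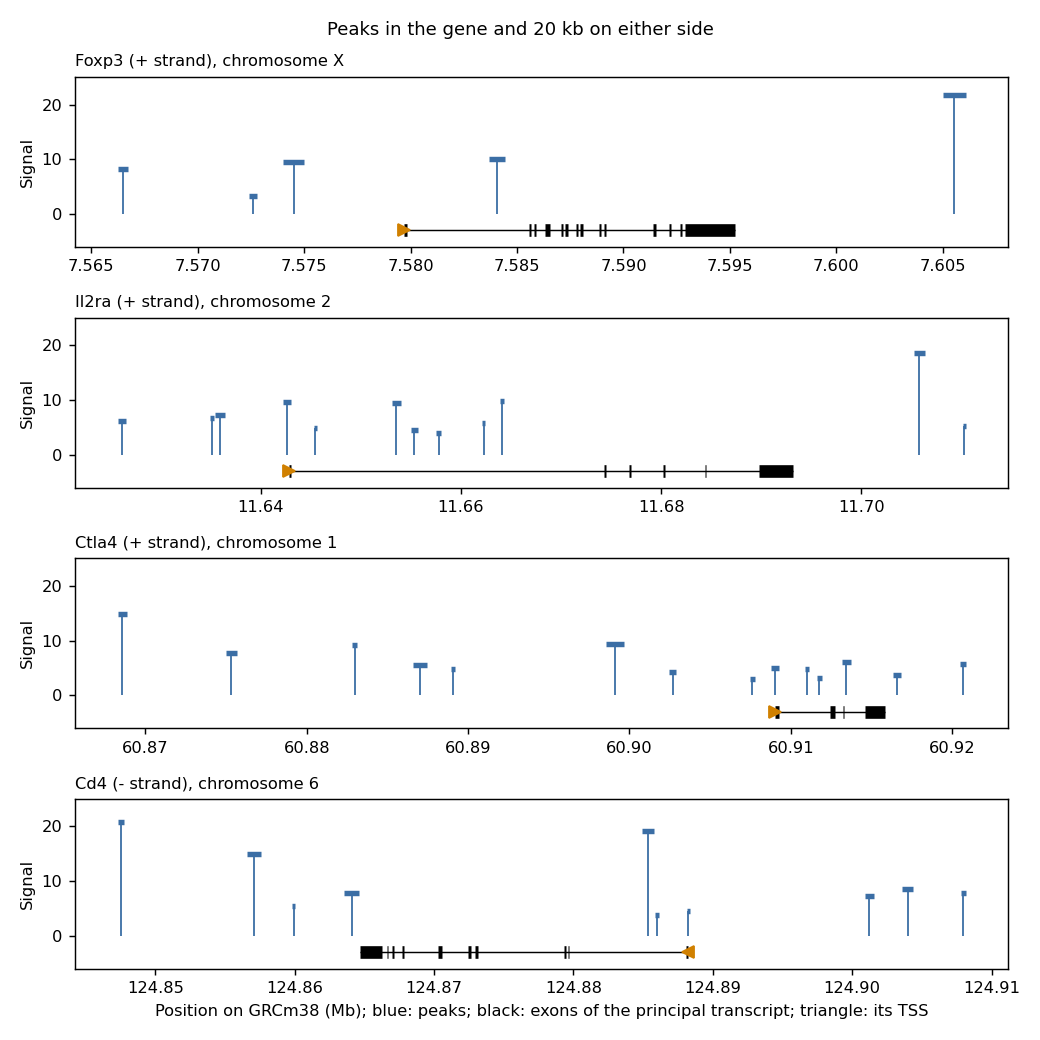
Peaks at Foxp3, Il2ra, Ctla4 and Cd4 on GRCm38 (position in Mb, signal on the vertical axis). Horizontal blue marks span each peak, black boxes are exons of the principal transcript and the triangle marks its TSS. Foxp3 had 5 peaks, Il2ra 12, Ctla4 14 and Cd4 10.

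Marker genes of several other cell types had few promoter peaks, with exceptions. None of 15 hepatocyte genes had one (interval 0 to 21.8%), Alb, Apoa1 and Apob among them. Of 9 NK cell genes only Eomes had one (6.77), and Ncr1, Klrb1c and Klrc1 had none. Of 15 muscle genes 3 had one, Actn2 (22.9), Tnni3 (18.4) and Ckm (11.9), and Myod1, Myog and Myf5 had none. The Ckm summit lay 66 bp from a TSS of the neighbouring gene Klc3 and 606 bp from one of Ckm. The hepatocyte, NK and muscle lists stood at percentiles 0, 0.690 and 0.825 of random lists, but with matching on promoter CpG ratio the NK list stood at 15.2 and the muscle list at 3.99. In contrast, all 20 housekeeping genes had a promoter peak (83.2 to 100%), with Rplp0 (26.5), Psmb2 (23.6) and Rab7 (22.5) highest.

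Among blood cell lineages, 5 of 15 B cell genes had a promoter peak (33.3%, 11.8 to 61.6%; percentile 7.32), with high signals at Fcmr (24.8), the complement receptor gene Cr2 (23.7) and Pax5 (18.6). Cd79a and Cd79b were among those without. Of 17 myeloid genes 5 had one (29.4%, 10.3 to 56.0%; percentile 3.13), led by Cebpa (14.9), Spi1 (13.0) and Fcgr3 (10.9), while Csf1r, Lyz2 and Itgam had none. Erythroid and megakaryocyte genes reached 6 of 12 (50%, 21.1 to 78.9%; percentile 43.4), led by Itga2b (23.9), Klf1 (17.4) and Gata1 (14.5), and the globin genes Hba-a1, Hbb-bs and Hbb-bt had none. Of 9 stem and progenitor genes 2 had one (22.2%, 2.81 to 60.01%; percentile 4.34), Meis1 (11.2) and Hlf (11.04), and Kit, Cd34 and Hoxa9 had none. Cytotoxic genes reached 6 of 11 (54.5%, 23.4 to 83.3%; percentile 54.2), with the perforin gene Prf1 (19.3), Fasl (18.02) and Gzma (12.5) highest, and Cd8a, Gzmk and Nkg7 had none. Neuron genes reached 5 of 15 (33.3%; percentile 7.38), with Syn1 (22.8), Dlg4 (19.1) and Gad2 (11.7), and Snap25, Rbfox3 and Neurod1 had none. Epithelial genes reached 3 of 12 (25%; percentile 3.32), Krt10 (14.9), Krt1 (11.1) and Cdh1 (10.6), and Krt5, Krt14 and Krt8 had none. With lists matched on promoter CpG ratio, the cytotoxic list rose to percentile 98.2, the erythroid list to 96.2, the B cell list to 70.6 and the myeloid list to 31.8, and the stem cell and neuron lists fell to 0.270 and 1.25. With peaks of at least the median −log10 p, chosen after seeing the data, the B cell list fell to 0.695, the myeloid list to 0.165, the erythroid list to 2.62 and the cytotoxic list to 4.30. With the pseudoreplicated list, in contrast, the share of B cell genes rose to 60% (percentile 56.7) and that of stem cell genes to 55.6% (percentile 44.7). Of the 29 promoter peaks in the B cell, myeloid, erythroid, stem cell, hepatocyte, neuron, muscle and epithelium lists, 2 had a summit closer to a TSS of another gene. Among the peaks named, those of Pax5, Fcgr3, Gata1, Itga2b, Dlg4, Tnni3, Krt1 and Krt10 lay near a TSS inside the gene, more than 1 kb from its 5′ end. With 5′ ends only, 8.33% of epithelial genes had a promoter peak.

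T cell loci also held many peaks, those at promoters included. The median number of peaks in the gene and 20 kb on either side was 8 for T cell identity, 7 for the Treg signature, 6.5 for resting T cells, 6 for the activation list and for inhibitory receptors, 5 for cytokine and chemokine receptors and 4 for effector Treg genes. The median over all protein-coding genes was 2. Among random lists of matched locus length, these 7 lists stood at percentiles from 99.2 (effector Treg genes) to 100. Hepatocyte and muscle genes had a median of 0 peaks (percentiles 2.16 and 2.19), NK cell genes also 0 (8.39), helper cytokines 1 (40.8), housekeeping genes 3 (94.98) and B cell genes 3 (89.6). The medians were 2 for cytotoxic (68.4), myeloid (71.6), stem cell (49.1) and neuron genes (51.5), and 1 for erythroid (31.9) and epithelial genes (34.7). The calls of the T cell lists ended with peaks of at least the median signal, where they ranged from percentile 39.0 (inhibitory receptors) to 94.4 (Treg signature). With peaks of at least the median −log10 p, chosen after seeing the data, the calls of effector Treg genes (45.5), resting T cells (91.1) and inhibitory receptors (87.2) ended, and with 5 kb on either side that of effector Treg genes (93.4). The hepatocyte call ended under all 5 alternatives (3.64 to 9) and the muscle call under 4 of 5 (7.35 to 15.7).

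The genes with most peaks in their locus were Gm20388 (143), Fgfr2 (55), Foxp1 (38), Gm20696 (36), Prkch (34), Bach2 (33), Akap13 (31), Arhgef3 (28), Gm37240 (26) and Inpp4b (26). Foxp1 and Bach2 encode transcription factors of lymphocytes, and Prkch encodes a protein kinase C of T cell signalling. Gene models of 4435 kb for Gm20388, 2961 kb for Fgfr2 and 1391 kb for Gm37240 span other genes, so their counts are not specific to them. The model of Gm20696 (99257484 to 99666797 on chromosome 6) overlaps that of Foxp1 (98925338 to 99522721), and their counts share peaks. Bach2 spans 347 kb, Foxp1 597 kb and Prkch 193 kb.

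Peak summits carried the binding motifs of some lymphocyte transcription factors, and those of others were depleted or had no call. The ETS consensus lay in 20.997% of summit windows and in 4.06% of windows 1 kb away, a ratio of 5.17 ± 0.090 (jackknife SE), and it was enriched at promoters (4.94 ± 0.138) and at distal peaks (5.33 ± 0.095). RUNX motifs were in 15.5% of summit windows, with a ratio of 2.12 ± 0.059 at distal peaks and 1.21 ± 0.030 at promoters. AP-1 (2.82 ± 0.101), the composite of BATF and IRF (9.75 ± 2.78), NF-kB (3.41 ± 0.113) and TCF/LEF (1.65 ± 0.061) were enriched at distal peaks, and at promoters their ratios were 1.13 ± 0.081, 0.933 ± 0.529, 2.00 ± 0.086 and 0.656 ± 0.041. In contrast, NFAT motifs were depleted also at distal peaks (0.787 ± 0.029), and T-box (0.902 ± 0.080) and ROR motifs (0.918 ± 0.101) had no call over all peaks. CTCF, the insulator protein, had the highest ratio over all peaks, 31.4 ± 2.93, and was in 8.20% of distal and 2.36% of promoter windows.

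Motifs of general promoter factors showed the opposite distribution. KLF/SP motifs were in 38.5% of promoter and 5.47% of distal windows, with ratios of 9.33 ± 0.275 and 3.12 ± 0.129. NRF1 (26.0 ± 3.50 at promoters), CREB (18.5 ± 3.12), YY1 (14.4 ± 2.84) and NFY (7.34 ± 0.417) had higher ratios at promoters than at distal peaks, where they were 4.87 ± 0.804, 6.98 ± 1.55, 4.11 ± 0.423 and 1.5 ± 0.066. The FOX consensus was enriched at distal peaks (1.41 ± 0.071) and depleted at promoters (0.717 ± 0.057). NFAT (0.632 ± 0.022) was depleted over all peaks. Motifs of other lineages went both ways: TEAD (0.388 ± 0.021) and HNF4 (0.442 ± 0.093) were depleted, and GRHL (1.95 ± 0.381, in 40 windows) was enriched. The GRHL call ended under 3 of 6 alternatives. MEF2 had no call over all peaks (1.21 ± 0.117) and was enriched at distal peaks (1.545 ± 0.186). PU.1 (2.82 ± 0.079), an ETS factor of myeloid and B cells, was enriched. Its consensus RAGGAAGT shares GGAAG with the ETS consensus CMGGAAGY, so the search cannot tell it from other ETS factors. GATA motifs, which are not specific to other lineages, were depleted over all peaks (0.881 ± 0.018), but their ratio was 1.12 ± 0.030 at distal peaks. Of the 28 motifs 20 were enriched over all peaks. Summit windows had a GC content of 53.8%, against 45.8% in windows 1 kb away, and the content was 61.3% at promoter and 48.8% at distal summits. Against dinucleotide-shuffled windows, chosen after seeing the data, NRF1 fell from 18.9 to 8.61, KLF/SP from 6.88 to 3.62 and NF-kB from 2.81 to 1.76, while YY1 rose from 9.71 to 16.8 and ISRE from 1.79 to 5.35. In the same windows GATA rose to 1.19 and C/EBP fell from 3.14 to 0.749, and the calls of NFAT (0.959 ± 0.037), GRHL (1.19 ± 0.194) and E-box motifs (1.01 ± 0.010, from 1.17) ended. A motif names a family of factors, and no binding was measured.

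**Figure D4:**
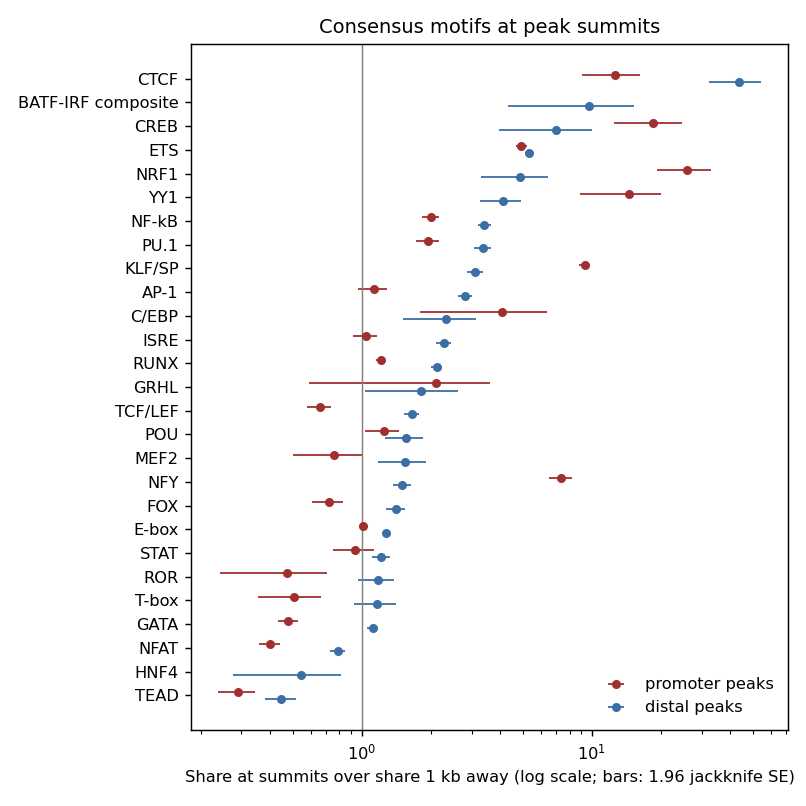
Ratio of the share of 200 bp summit windows with each consensus to the share of windows 1 kb away (log scale), at promoter (red) and distal (blue) peaks, with bars of 95% jackknife intervals; points that rest on under 20 windows are left out. CTCF is highest at distal peaks (43.4) and NRF1 at promoters (26.0).

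Promoter peaks were stronger and wider than distal ones. The median signal was 15.4 at 13691 promoter peaks and 12.1 at 20919 distal peaks, a ratio of 1.27 ± 0.015 (jackknife SE). Each peak took the signal of its highest summit. The median number of summits was 2 at promoters and 1 in exons, introns and intergenic sequence, which favours promoters, and how much this adds was not tested. The median width was 911 bp at promoters, 560 bp in introns and 568 bp in intergenic sequence. Over deciles of signal, promoters made up 32.0% of the peaks in the lowest and 62.0% in the highest, with the smallest share, 27.4%, in decile 3. The ratio of the median −log10 p, chosen after seeing the data, was 2.77 ± 0.079, which is not a fold of enrichment.

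The promoter peaks of regulatory T cell genes, like those of several other T cell lists, ranked low among promoter peaks by signal and less low by −log10 p. The 19 promoter peaks of the Treg signature had a median signal of 9.28 and a median percentile of 26.7 among all peaks, whereas the promoter peaks of all 11521 genes had a median percentile of 70.9. By −log10 p, the same peaks had a median percentile of 64.9, against 80.5 for all genes. The activation list had median percentiles of 23.7 by signal and 78.2 by −log10 p, and T cell identity 39.1 and 73.2. Housekeeping genes were close to all genes by signal (69.7) and ranked high by −log10 p (88.8). B cell genes had the opposite order, 76.6 by signal and 42.3 by −log10 p, and so did erythroid and megakaryocyte genes, 53.1 and 27.9. These ranks were chosen after seeing the data. Among random lists of promoter peaks of the same size, the Treg signature stood at percentile 0 by signal and 1.90 by −log10 p.

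**Figure D5:**
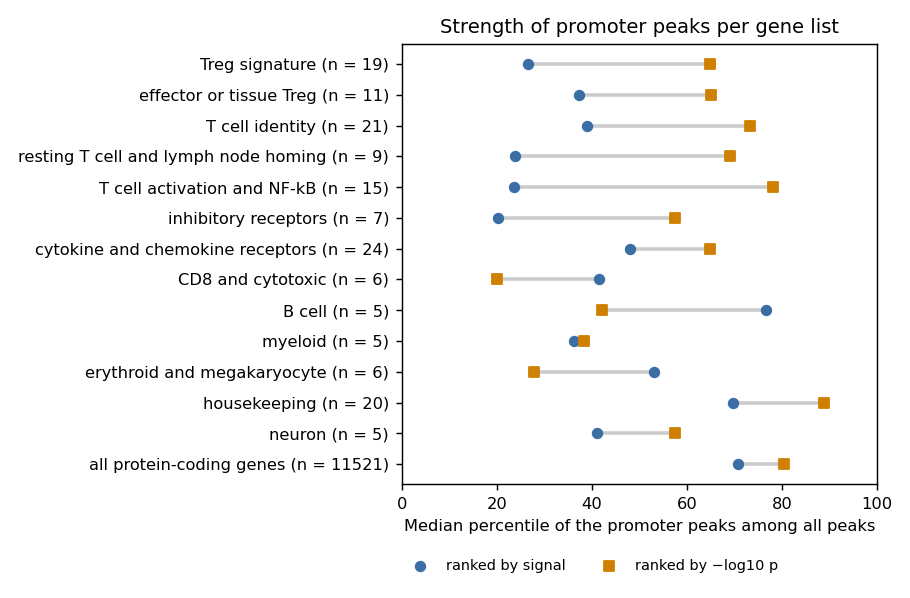
Median percentile among all peaks of the promoter peaks of each list with 5 or more of them, ranked by signal (blue circles) and by −log10 p (orange squares). The Treg signature moved from 26.7 by signal to 64.9 by −log10 p, and B cell genes from 76.6 to 42.3.

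Peaks were sparse on the X chromosome. A male carries a single copy of it, but whether this lowers the number of peaks was not tested. The X had 834 peaks, or 5.10 per Mb outside gaps, below every autosome. The autosomes ranged from 10.7 per Mb on chromosome 14 to 19.1 on chromosome 11, with a median of 13.6, which is 2.67 times the density of the X. Per protein-coding gene the X had 0.880 peaks and the autosomes 1.08 to 2.46. The median signal of the peaks on the X was 14.5, against 13.2 on the autosomes. The Y chromosome had 13 peaks, or 0.148 per Mb.

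The 10 peaks of highest signal mostly lay away from promoters of protein-coding genes. The highest, 64.7, was at 69355469 to 69355735 on chromosome 2, an intergenic site 12.98 kb from the nearest coding TSS, that of Abcb11. The next was at 143482934 to 143483180 on chromosome X (62.7, nearest coding gene Pak3 at 35.5 kb). It was followed by peaks in an intron at 96077511 to 96077951 on chromosome 10 (48.6, Gm5426 at 58.9 kb) and at 60042667 to 60043155 on chromosome 5 (47.5, G6pd2 at 1766 kb). The remaining 6 had signals from 38.4 to 44.2. Their nearest coding genes were Gnb1l (15.5 kb), Gm13283 (2.41 kb), Igf2bp3 (21.55 kb), Gm20594, Nxph1 (940 kb) and Pdcd1 (417 kb). The peaks listed for Gm13283 and Pdcd1 lay within 1 kb of an annotated TSS that is not of a coding gene. Only the peak near Gm20594, at 0.40 kb, had its summit within 1 kb of a coding TSS. Of these 10 peaks, 5 matched the mitochondrial genome.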

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

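The ranked list held 170 lines past the IDR threshold that are not in the thresholded list, a signal in data that the comparisons above do not use, which is why they are listed here. They formed 78 intervals, with 61 of the lines on unplaced contigs and 109 on chromosomes. The thresholded and pseudoreplicated lists held 0 intervals on contigs, against 82 in the ranked list, so the 61 lines are absent along with every other contig entry. On chromosomes the highest by −log10 p were at 103648978 to 103649358 on chromosome 6 (signal 45.8), at 24611571 to 24616152 on chromosome 1 (signal 2.56) and at 98666172 to 98667365 on chromosome 2 (signal 8.90). The test on them, which was chosen before its result was seen, is given with the peaks of highest −log10 p below.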

How the results depend on the processing

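The settings with −log10 p, with coding neighbours left out and with shuffled windows were chosen after seeing the data. No leave-one-replicate-out was possible because all lists are pooled, and no paired analysis was possible because there is 1 biological replicate. The cause of the changes below was not tested. Over all settings, 114 of 152 percentiles of promoter share, 73 of 95 percentiles of peaks per locus and 150 of 168 motif ratios kept their call. A list or motif without a call counted as kept when it stayed without one, however far its value moved. Of the values of peak location, 5 of 40 stayed close to the main value. None of the 4 strength ratios and none of the 2 density ratios did.

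With peaks of at least the median signal, the number of peaks was 17305, the promoter share 48.4% and the median autosomal density 2.37 times that of the X chromosome. The promoter share of the Treg signature fell to percentile 0.455 of random lists, the activation list to 1.65, inhibitory receptors to 0.910, cytokine and chemokine receptors to 21.7, T cell identity to 50.2 and housekeeping genes to 96.7. The myeloid list stood at 0.105, stem cell genes at 0.540, neuron genes at 1.66 and epithelium at 1.39. The peaks per locus stood at percentile 94.4 for the Treg signature, 92.3 for T cell identity, 45.3 for effector Treg genes, 42.3 for resting T cells, 52.7 for the activation list, 39 for inhibitory receptors, 44.995 for cytokine and chemokine receptors, 7.29 for hepatocyte genes and 7.35 for muscle genes. The motif ratios of STAT (0.981) and FOX (0.979) fell below 1.

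With peaks of at least the median −log10 p, the promoter share of the Treg signature stood at percentile 95.9, the B cell list at 0.695, the myeloid list at 0.165, stem cell genes at 0.250, muscle genes at 2.99 and epithelium at 0.045. The peaks per locus stood at 45.5 for effector Treg genes, 91.1 for resting T cells, 87.2 for inhibitory receptors, 7.76 for hepatocyte genes and 8.29 for muscle genes. The ratio of the median −log10 p of promoter peaks to that of distal peaks was 2.77.

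With the pseudoreplicated list, the promoter share was 30.9%, the exon ratio 1.16, the strength ratio 1.62 and the density ratio to the X chromosome 2.48. Promoter percentiles were 99.5 for effector Treg genes, 99.2 for resting T cells, 99.4 for inhibitory receptors, 8.56 for helper cytokines and 1.21 for the myeloid list, and the peaks per locus of hepatocyte genes stood at 6.17. Counting every line gave 68653 entries.

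With promoters within 500 bp, the promoter share was 34.6%, the exon ratio 1.08 and the strength ratio 1.36, and inhibitory receptors stood at percentile 97.7 and the myeloid list at 0.270. With promoters within 2500 bp, the promoter share was 48.2% and the strength ratio 1.16, and resting T cells stood at percentile 99.96, inhibitory receptors at 99.6, the myeloid list at 2.19 and epithelium at 2.41. With TSSs of protein-coding genes, the promoter share was 35.5% and the exon ratio 1.11. With the 5′ end of the gene only, the myeloid list stood at 2.18 and epithelium at 0.270.

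With random lists matched on CpG ratio, the percentiles were 99.975 for inhibitory receptors, 25.8 for helper cytokines, 98.2 for cytotoxic genes, 15.2 for NK cell genes, 0.270 for stem cell genes, 1.25 for neuron genes and 3.99 for muscle genes. Without genes with a coding neighbour, inhibitory receptors stood at 97.8 and NK cell genes at 3.12. With loci of 5 kb on either side, the peaks per locus stood at 93.4 for effector Treg genes, 98.3 for housekeeping genes, 9 for hepatocyte genes and 8.13 for muscle genes. With 50 kb, they stood at 98.7 for housekeeping genes, 3.64 for hepatocyte genes and 15.7 for muscle genes. Against dinucleotide-shuffled windows, GATA (1.19) and ROR (1.72) rose above 1, C/EBP (0.749) fell below it and the calls of NFAT (0.959), E-box (1.01) and GRHL (1.19) ended. MEF2 rose from 1.21 to 3.90 in the same setting. The call of GRHL also ended with windows of 100 bp (2) and with peaks of at least the median signal (1.71), that of STAT with windows of 100 bp (1.07) and without masked windows (1.06), and that of FOX without masked windows (1.06).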

Other observations

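The tests on the −log10 p of Treg promoters, against all peaks and against random lists of promoter peaks, and on the 9 strong peaks of other lineages were chosen only after the result was seen. The tests on neighbouring peaks as the whole cause and on CpG-rich promoters were added after the results of the other tests. The rule that an explanation is argued against only where the 95% interval leaves out the range it needs was also set after the values were seen. This rule and the test on the 9 peaks changed 3 readings, all named below. The design names no second group, so no biological explanation that rests on a difference between groups was tested, and the tests on accessibility, CTCF and CpG concern properties of these promoters.

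Apart from 2, the 10 peaks of highest −log10 p lay 8.33 to 1766 kb from the nearest coding TSS. Of the top 10, 7 matched the mitochondrial genome over at least 100 bp at 90% identity or more, whereas 19 of all 34610 peaks (0.05%) did, so nuclear copies of mitochondrial DNA may account for these 7. Repeats marked in the reference were argued against, since the median share of masked bases around the 10 summits was 5%. The peak at 143482934 on chromosome X had no mitochondrial match and stays open, and the other 2 lay at the promoters of Hjurp and Sel1l, genes named after their values were seen. For most of the 51 left-out intervals on chromosomes mitochondrial copies were argued against, since 1.961% of them matched (exact 95% interval 0.05 to 10.45%), but that 1 interval, on chromosome 1, held 15 of the 109 lines, and the 27 intervals on contigs were not tested.

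Promoter peaks of the Treg signature had a low enrichment for their −log10 p. A local background raised by other peaks may lower it: at the same decile of −log10 p, peaks with 2 or more others within 5 kb had 0.438 times (jackknife SE 0.009) the signal of peaks with none, and 8 of the 19 Treg promoter peaks had such neighbours, against 4.92% for all genes. Among peaks of the same decile and number of neighbours, the Treg promoters had a median percentile of 17.8 (bootstrap 95% interval 10.85 to 27.96). This argued against the presence of 2 or more others within 5 kb as the whole cause. That median met the bound of 25 written beforehand. The rule first applied also asked for the whole interval to lie below 25 and left this reading undecided. The matching left out the strength of neighbours and peaks beyond 5 kb. It therefore cannot decide on the local background as the whole cause. Weak accessibility of these promoters stays open, because their median −log10 p stood at percentile 64.9 of all peaks with a bootstrap interval of 32.3 to 76.6, although by the first rule, without the interval, it was argued against. Weaker peaks than at other promoters also stay open, with that median at percentile 1.90 of random lists of promoter peaks, a value that had been seen before the test was written.

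Some marker genes of other lineages, Fcmr, Cr2, Itga2b, Actn2 and Syn1 among them, had promoter peaks of high signal. In all, 9 of the 29 promoter peaks of the 8 lists exceeded the median percentile of all promoter peaks (70.9). That is a smaller share than the 50% that a median gives, but its exact interval, 15.3 to 50.8%, includes 50%. By signal the B cell (76.6) and muscle lists (75.6) had median percentiles above 70.9, and the other lists with promoter peaks lay below it. By −log10 p the B cell (percentile 1.26 of random lists of promoter peaks), erythroid (0.08), epithelium (0.15), stem cell (0.82) and myeloid lists (0.93) ranked low, while neuron (6.45) and muscle genes (9.82) stayed within the central 95%. For the promoter of another gene nearby, 6.90% of the 29 summits (0.85 to 22.8%) and 0 of the 9 (0 to 33.6%) lay closer to a TSS of another gene. These shares cannot decide, because each peak was chosen for overlapping the 1 kb around a TSS of its marker gene. In the T cell identity and Treg signature lists, 4 of 40 lay closer. The summits of the 9, however, lay 1777 (Pax5) to 45210 bp (Cr2) from the nearest TSS of another gene. This argued against that explanation for the 9. Among the weaker peaks, those of Ebf1, Cebpa, Cebpb and Ckm had such a TSS within 1 kb. CTCF sites in the promoter window stay open. Of the 29, 0% held the consensus (0 to 11.9%), which by the first rule argued against them. For the 9, the interval of 0 to 33.6% reached the 25% needed, and 9 peaks are too few for any count to leave that out. Of all promoter windows, 2.36% held the consensus. CpG-rich promoters stay open. Of the 29 genes, 31.0% (15.3 to 50.8%) reached the median CpG ratio of genes with a promoter peak, and of the 9, 11.1% did (0.28 to 48.3%). By the rule above, the 29 left the question undecided and the 9 argued against CpG-rich promoters at those peaks. The ratio, however, was taken at the 5′ end of each gene. Several of the 9 peaks, those of Pax5, Itga2b, Dlg4 and Tnni3, lay near another TSS, so the test cannot decide for them.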
